A study of Arabidopsis thaliana with 6 samples.

How the data were processed

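Transcript levels were measured in root cells of Arabidopsis thaliana on 6 one-colour Affymetrix arrays, 1 array per sample. The cells came from line J0121, an enhancer trap line in which green fluorescent protein marks the xylem pole pericycle, the cell layer from which lateral roots start. Per the labels' protocols, seedlings were grown on 10 µM NPA, an inhibitor of auxin transport, for 72 hours after germination. Cells were taken then (0 h) or after 2 h or 6 h on 10 µM NAA, a synthetic auxin, and were isolated by fluorescence-activated sorting. Each of the 3 time points had 2 arrays, which the labels call biological replicates. Per the labels' protocols, the total RNA was too little to be detected before biotin labelling.

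The deposited values are signal intensities on a linear scale, 1 per probe set. The submitters' processing notes name MAS5 for them, and its version is not given in the sources used here. The authors' scaling was read from the values: the mean left after trimming 2% of the probe sets at each end was 250.0 on every array. For the array of replicate 1 at 2 h the authors also deposited a detection p-value and a call for each probe set. Its signals were identical to those in the series table, and its calls served only as a description. Array medians ran from 75.8 to 109.9 signal units. Arrays have no read depth, so the number of arrays limits the precision.

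Signals were analysed as log2(signal + 5) with the authors' scaling kept. The pseudocount of 5 was the 10th percentile of all signals, and log2 changes of dim probe sets are understated on this scale. Of 22810 probe sets, 64 Affymetrix controls were left out. The 13647 with a mean log2 value above the 40th percentile were tested, and 9099 lay below it. Such a filter on the mean also leaves out transcripts that were bright at 1 time point only. All 6 arrays entered 1 fit with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3, in which the 3 groups shared 1 estimate of the spread. The fit had 3 residual and 8.26 prior degrees of freedom. Contrasts were 2 h versus 0 h, 6 h versus 0 h and 6 h versus 2 h, with an F test over the time points. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes come from this limma fit.

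Gene names came from a table that pairs the array's probe sets with genes. It lists 13513 probe sets with 1 gene and 503 with several, and the other 8794 are unnamed here. Of the 13513, 13436 matched a locus of the TAIR10.1 annotation, which was used for names and gene spans, and no coordinates are given. Among tested probe sets 7429 had 1 locus. Names were taken only from probe sets with 1 gene, and a locus with several was represented by the one with the highest mean.

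Before the data were examined, 25 gene lists with 385 members were fixed, together with the rule for naming genes. For 366 members the annotation gave the listed symbol, and for 19 it did not. These were kept under the annotation's name. The lists of SAUR genes, ARF transcription factors, D-type cyclins with E2F/DP and RBR, cytokinin oxidases, ACC synthases, and markers of stele and pericycle, xylem, root cap and green tissue had 0 named members, and are not analysed here. Of the A-type response regulators 2 were named and 0 tested. Lists of cytosolic ribosomal proteins, of mitotic kinesins, condensins and spindle proteins, of DNA polymerases with RFC and RPA, and of chloroplast-encoded transcripts were added after the files were seen and before any test. Each list with at least 3 tested members (12 lists) was tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation. Tested were 3 of 28 listed Aux/IAA genes, 4 of 8 GH3 genes, 3 of 29 lateral root regulators and 4 of 35 DNA replication genes. Of the G2 and mitosis list 3 of 37 were tested, and of the ribosomal protein list 118 of 207. The list results hold for the tested members alone. Genes named in each comparison were the 10 largest rises and 10 largest falls among calls with 1 locus and no overlap between the replicates, up to 4 called members of each list, and 13 anchor genes whatever their result. Of the 13, only 3 could be tested (GH3.3, LBD16 and LBD29). ACR4 was named but lay below the filter.

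Alternatives fixed at the same time were a pseudocount 4 times smaller or larger, no filter or a filter at the 60th percentile, quantile normalization, centring on the median, eBayes without the trend or with robust estimation, the replicate number as a block, leaving out each array, a fit of only the 4 arrays compared, an added 2-fold minimum, and the estimated correlation. A block for the brightness of the hybridisation controls was added after seeing the data, as was a split in which each 0 h array served 1 comparison. Overlaps between comparisons that share the 0 h arrays were set against 100 simulations of unchanged groups.

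The fit was tested on simulated data made from the real means and spreads, with 13647 probe sets passing the filter. For 2 h versus 0 h it recovered 4.48% of the changes of 2-fold, 56.7% of those of 4-fold and 80.3% of those of 8-fold. For 6 h versus 0 h the shares were 11.9%, 68.7% and 83.3%, and for 6 h versus 2 h 8.96%, 56.7% and 75.8%. Unchanged probe sets called numbered 9, 2 and 6 in these comparisons. Each simulation changed 67 probe sets by 2-fold, 67 by 4-fold and 66 by 8-fold, far fewer than were called in the data. The Benjamini-Hochberg threshold depends on how many probe sets change, so these shares do not measure the sensitivity in the data. In a simulation of 6 h versus 0 h on 13647 probe sets, camera called the 1 raised list of 20 and 0 of 100 unchanged lists. The simulated noise was independent between probe sets, so lists with correlated members were not tested. In the data the estimated correlations within lists ran from -0.161 (histones) to 0.602 (DNA replication).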

Results

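The series follows sorted xylem pole pericycle cells from an arrested state into the first steps of lateral root initiation. Its design text places the cells at an arrest before S phase at 0 h, in auxin signalling and passage from G1 to S at 2 h, and near mitosis or the asymmetric division at 6 h. There were 3 groups of 2 arrays. Arrays without NAA at the later times were not analysed here, so time on NAA and age of the seedlings went together. Replicates correlated across probe sets at r = 0.870 at 0 h, 0.938 at 2 h and 0.920 at 6 h. The first principal component held 61.7% of the variance and ordered the arrays by time, and the second held 16.9%. The median residual SD was 0.39 on the log2 scale. Between any of the time points 4045 of 13647 probe sets (29.6%) differed in limma's F test, and 2616 and 2643 did without replicate 1 or 2 at 6 h.

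Within each time point 1 array had brighter hybridisation controls, transcripts that are not from the plant and are added before hybridisation, than the other. Their geometric mean signal was 17817 on replicate 1 and 3351 on replicate 2 at 0 h, 2430 and 7932 at 2 h, and 3768 and 12857 at 6 h. The 25S rRNA control read 17466 on replicate 2 at 2 h and 12014 on replicate 2 at 6 h, against 5396 to 6564 on the other 4 arrays. The ratio of the 3' to the 5' actin control, a sign of RNA quality and labelling, was 2.22 and 1.40 at 0 h, 2.98 and 1.37 at 2 h, and 4.48 and 3.84 at 6 h (replicates 1 and 2). That of the ubiquitin controls was 8.31 and 5.99, 6.13 and 9.71, and 8.81 and 10.7, and that of the GAPDH controls 5.78 and 2.68, 4.73 and 3.93, and 4.37 and 3.42. The split by hybridisation controls crossed the time points, so values within the brighter and the dimmer arrays are given beside the list results.

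**Figure D1:**
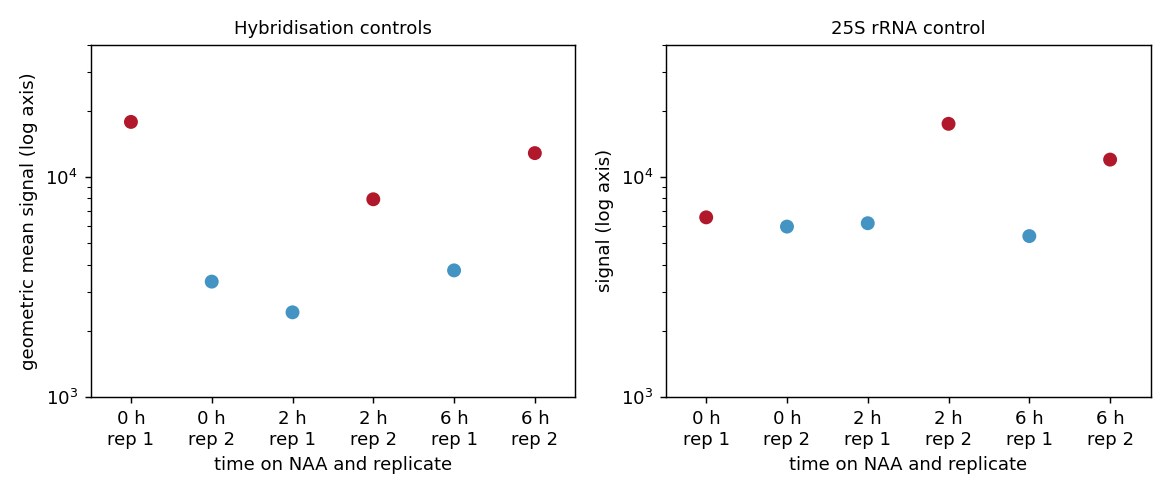
Geometric mean signal of the hybridisation controls (left) and signal of the 25S rRNA control (right) on each of the 6 arrays, on log axes; red points mark the brighter and blue points the dimmer array of each time point by hybridisation controls. The brighter array of each pair lies at 7932 or above on the left and the dimmer at 3768 or below.

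After 2 h on NAA, 3 of 4 GH3 genes of the auxin response and all 3 tested regulators of lateral root formation rose. GH3.1, which encodes an enzyme that conjugates auxin to amino acids, rose by 5.28 ± 0.39 on the log2 scale (SE, n = 2 arrays per group), a 38.7-fold change. PUCHI, an AP2-type transcription factor of the lateral root primordium, rose by 4.56 ± 0.43, and LBD16 and LBD29, transcription factors of lateral root initiation, by 2.04 ± 0.33 and 2.08 ± 0.41. The expansin gene EXPA4, of a family that loosens cell walls, rose 39.4-fold. Of 118 genes for cytosolic ribosomal proteins 83 rose, with a list median of 1.54 on the log2 scale. With an estimated correlation the GH3, lateral root and ribosomal lists were not called (adjusted p = 0.147 for each).

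In all, 991 probe sets were higher and 562 lower at 2 h than at 0 h (11.4% of those tested, limma), of which 536 and 264 had 1 named locus. The median of all tested probe sets was -0.15. Centring each array on its median moved it to 0.12 and quantile normalization to -0.02, so the medians of the ribosomal protein list, and of the chloroplast-encoded list where it was called, are also given relative to it. With that centring 82.4% of the calls were higher, against 63.8% with the authors' scaling.

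Of 4 tested GH3 genes 3 rose and 0 fell (3 and 0 adjusted over the list alone). WES1, also known as GH3.5, went from a signal of 2679 ± 151 to 12889.6 ± 599 (SD, n = 2), a log2 change of 2.26 (adjusted p = 0.00152, limma). GH3.3 rose by 2.15 ± 0.46 (adjusted p = 0.0123), and GH3.17 had a change of 0.38 ± 0.52. The list was called (adjusted p = 1.31e-04, camera; adjusted p = 0.147 with an estimated correlation), with medians of 2.62 in the brighter and 1.8 in the dimmer arrays. Of 3 tested Aux/IAA genes, which encode repressors of auxin signalling, 2 rose by both counts: IAA29 by 3.76 ± 0.45 and IAA30 by 2.49 ± 0.61. IAA18 had a change of 0.94 ± 0.47. That list was called too (adjusted p = 0.00258, camera; adjusted p = 0.147 with an estimated correlation), with medians of 1.28 and 3.94 in the brighter and dimmer arrays. All 3 tested lateral root regulators rose, by both counts (adjusted p = 1.06e-04, camera; adjusted p = 0.147 with an estimated correlation), with medians of 2.07 and 2.78.

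Of the 118 ribosomal protein genes 83 rose and 0 fell; adjusted over the list alone, 100 rose and 1 fell. The list's median was 1.69 relative to all tested probe sets, and 1.79 and 1.31 in the brighter and dimmer arrays (adjusted p = 1.16e-39, camera; adjusted p = 0.147 with an estimated correlation). Its largest rises were AT5G59240 (3.53 ± 0.32), AT5G39850 (2.92 ± 0.32), AT3G06680 (2.77 ± 0.43) and AT1G15250 (2.74 ± 0.33). Of 4 tested genes of nucleolar and ribosome assembly 3 rose (4 adjusted over the list alone). AT5G14520, the Pescadillo homologue that acts in ribosomal RNA maturation, rose by 2.57 ± 0.34 and AT3G15460 by 2.09 ± 0.34. PGY1 rose by 1.20 ± 0.32. PGY1 and AT3G09630 encode ribosomal proteins and are also in the ribosomal protein list. This list was called at an adjusted p of 1.31e-04 by camera (adjusted p = 0.147 with an estimated correlation), with medians of 1.90 and 1.40.

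Other lists were not called at 2 h. Of 6 expansin and XTH genes 2 rose, EXPA4 and EXPA15 (1.74 ± 0.38), 0 fell, and the counts adjusted over the list alone were the same (list adjusted p = 0.133, camera). DNA replication (4 genes, adjusted p = 0.215), replication-dependent histones (4 genes, 0.241), the Aurora kinases of the G2 and mitosis list (3 genes, 0.694), mitotic kinesins with condensins (13 genes, 0.467), the polymerase list with RFC and RPA (3 genes, 0.177) and chloroplast-encoded transcripts (69 genes, 0.215) had 0 members called (limma). At an unadjusted p under 0.05, 1 gene each of the replication, histone, kinesin and polymerase lists was higher, 3 chloroplast-encoded transcripts were lower, and 0 Aurora genes passed. Adjusted over the list alone, 1 histone gene and 1 gene of the polymerase list passed. WRKY53, a stress-responsive transcription factor, rose by 1.91 ± 0.41, while STZ had a change of 0.91 ± 0.40 (1 of these 2 stress genes rose, and both when adjusted over the list alone). WAG2, SIM, GSO1 and the phloem, cortex and epidermis markers AT3G12730, AT1G09750 and EXPA18 were not called by either count. Each was the only tested member of its list, so its second count is at an unadjusted p under 0.05.

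Among called genes with 1 locus and no overlap between the replicates, the largest rises were AT3G28420 (5.91 ± 0.48), AT2G39870 (5.37 ± 0.48), EXPA4 (5.30 ± 0.48), GH3.1 and AT1G68400 (5.23 ± 0.58). AT3G28420 started from a signal of 3.8 ± 0.99, so its fold depends on the pseudocount. AT5G17340 (4.61 ± 0.92), PUCHI, AT1G03820 (4.56 ± 0.38), TBL36 (4.55 ± 0.34) and AT3G28840 (4.27 ± 0.37) followed. The largest falls were AT2G28780 (-5.33 ± 0.72), AT3G01260 (-5.18 ± 0.66) and AT3G20015 (-4.73 ± 0.47). Changes of -4.16 to -3.29 were seen for AT1G19530, AT2G16980, AT5G10580, AT1G49570, a class III peroxidase gene, AT4G00910, AT4G30450 and ATSBT5.2, a subtilase gene. There were 656 calls without replicate 1 at 2 h, 473 without replicate 2, and 1242 with the hybridisation controls as a block, which ended the calls of IAA30 (adjusted p = 0.0550, limma) and PGY1 (0.0568). Without replicate 2 at 2 h the adjusted p (limma) was 0.0953 for GH3.3, 0.0553 for LBD29, 0.0521 for IAA30, 0.134 for EXPA15, 0.123 for WRKY53, 0.276 for PGY1, 0.0737 for AT5G17340 and 0.0981 for AT1G19530, and without replicate 1 it was 0.0530 for GH3.3, 0.0683 for LBD29, 0.157 for IAA30 and 0.0890 for PGY1.

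**Figure D2:**
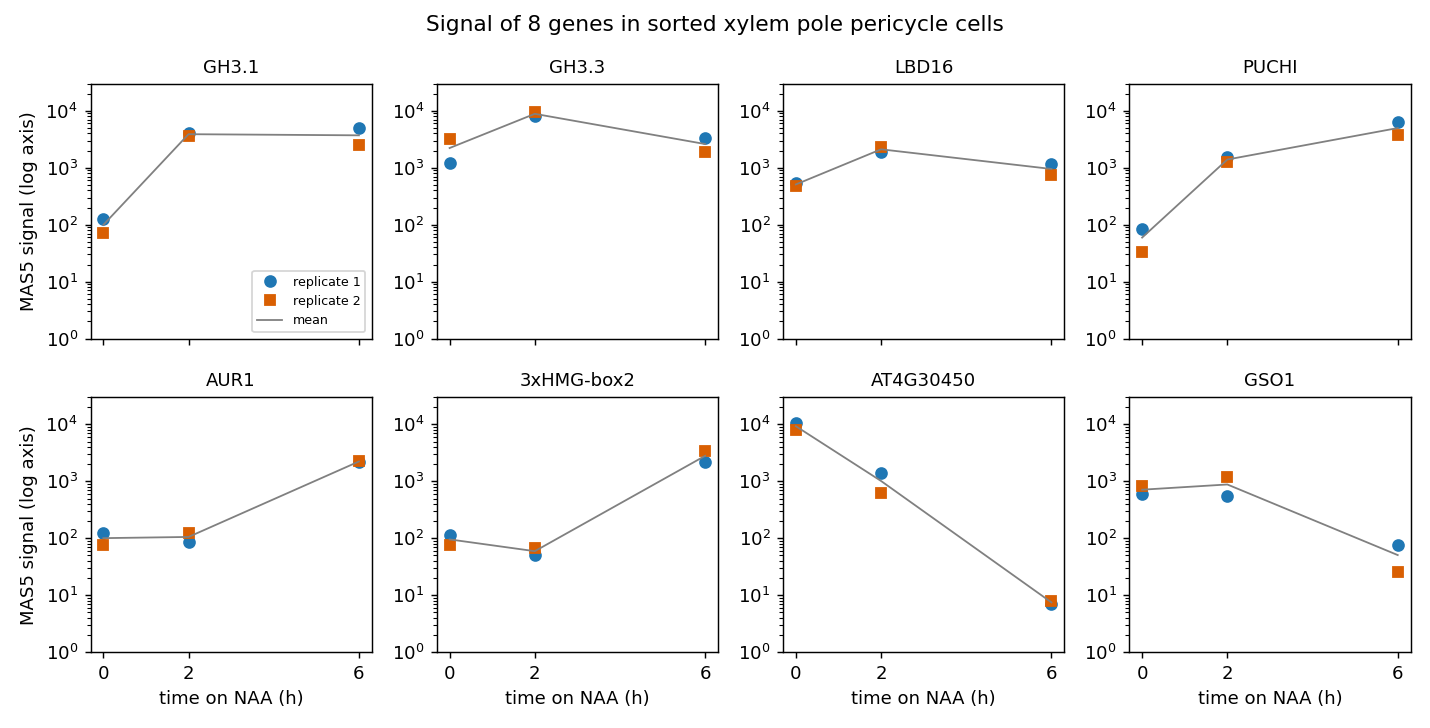
MAS5 signal (log axis) of 8 genes against time on NAA in hours; circles and squares are the replicate arrays and the grey line joins their means. GH3.1 went from a mean of 99.2 at 0 h to 3884 at 2 h, AUR1 stood at 101 and 106 at 0 h and 2 h and at 2237 at 6 h, and AT4G30450 went from 9311 to 7.5 between 0 h and 6 h.

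After 6 h, all 3 Aurora genes, 12 of 13 mitotic kinesin, condensin and spindle genes and 2 of 4 DNA replication genes were higher than at 0 h, beside 108 of 118 ribosomal protein genes. With an estimated correlation none of these lists was called (adjusted p = 0.319 for DNA replication and 0.158 for each of the others). AUR1, which encodes a mitotic Aurora kinase, rose by 4.44 ± 0.36 and AUR2 and AUR3 by 3.73 ± 0.55 and 3.44 ± 0.46. The kinesin list had a median of 4.06. PRL, which encodes the replication helicase subunit MCM7, rose by 2.59 ± 0.30. The largest fall of a named gene was that of AT4G30450, with a change of -9.53 ± 0.39. Its mean signal at 6 h was 7.5, so the size of this fall depends on the pseudocount.

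Against 0 h, 2297 probe sets were higher and 2315 lower at 6 h (33.8% of those tested, limma), with 1259 and 1135 of them at 1 named locus. The median of all tested probe sets was -0.11, and 0.01 after centring on the array medians, which gave 2322 higher and 1726 lower. With the hybridisation controls as a block 4296 probe sets were called. Without replicate 1 at 6 h 3026 were called. The list results at 6 h stood beside actin 3' to 5' ratios of 4.48 and 3.84, against 2.22 and 1.40 at 0 h, and GAPDH ratios of 4.37 and 3.42, which lay between those at 0 h (5.78 and 2.68).

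All 3 Aurora genes rose by both counts (adjusted p = 0.00135, camera; adjusted p = 0.158 with an estimated correlation), with medians of 3.86 and 3.6 in the brighter and dimmer arrays. In the kinesin and condensin list 12 genes rose and 0 fell, and all 13 rose when adjusted over the list alone (adjusted p = 6.94e-09, camera; adjusted p = 0.158 with an estimated correlation). Its medians were 3.73 and 3.96. Its largest rises were 3xHMG-box2 (4.80 ± 0.38) and 3xHMG-box1 (4.42 ± 0.55), which encode proteins of mitotic chromosomes, the kinesin gene KINESIN-12B (4.55 ± 0.80) and AT5G60930 (4.50 ± 0.71). The condensin gene ATSMC2 had a change of 1.27 ± 0.48 (adjusted p = 0.0614). BUBR1, a spindle checkpoint gene picked after its values were seen, lay below the filter, with a signal of 2.8 ± 1.56 at 0 h and 328 ± 67.7 at 6 h.

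Of 4 DNA replication genes 2 rose (2 adjusted over the list alone), PRL and ICU2, which encodes the catalytic subunit of DNA polymerase alpha (1.3 ± 0.45). The list was called (adjusted p = 0.0418, camera; adjusted p = 0.319 with an estimated correlation), with medians of 0.85 and 1.48 in the brighter and dimmer arrays. POLA3 (1.94 ± 0.38) and AT3G42660 (1.72 ± 0.38) rose among 3 genes of DNA polymerases, RFC and RPA (3 adjusted over the list alone; adjusted p = 0.0418, camera; adjusted p = 0.267 with an estimated correlation). That list's medians were 1.08 and 2.35. Of 4 histone genes HTB1 rose (1.20 ± 0.34; 2 adjusted over the list alone), and the list was not called (adjusted p = 0.128).

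Among ribosomal protein genes 108 rose and 0 fell (114 and 0 adjusted over the list alone), with a list median of 2.22, or 2.32 relative to all tested probe sets (adjusted p = 2.05e-34, camera; adjusted p = 0.158 with an estimated correlation). In the brighter and dimmer arrays the median was 2.20 and 2.1. Both ubiquitin 3' to 5' ratios at 6 h (8.81 and 10.7) also lay above those at 0 h (8.31 and 5.99). AT5G59240 rose by 4.52 ± 0.32, AT5G39850 by 3.83 ± 0.32, AT5G67510 by 3.58 ± 0.38 and AT4G30800 by 3.52 ± 0.35. All 4 genes of the nucleolar and ribosome assembly list, 2 of them ribosomal protein genes, rose by both counts (adjusted p = 7.24e-04, camera; adjusted p = 0.158 with an estimated correlation), with medians of 2.71 and 2.32. Their changes were 3.3 ± 0.34 for AT5G14520, 2.83 ± 0.34 for AT3G15460, 2.07 ± 0.37 and 1.87 ± 0.32 for the ribosomal protein genes AT3G09630 and PGY1.

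PUCHI reached 6.35 ± 0.43 and LBD29 2.06 ± 0.41, while LBD16 had a change of 0.86 ± 0.33 (adjusted p = 0.0658, limma). The lateral root list was called with 2 of 3 genes higher (3 adjusted over the list alone; adjusted p = 0.00864, camera; adjusted p = 0.267 with an estimated correlation) and medians of 1.49 and 2.62 in the brighter and dimmer arrays. ACR4, a receptor kinase gene of pericycle divisions, lay below the filter. Its signal was 4.2 ± 0.99 at 0 h, 8.9 ± 1.27 at 2 h and 135 ± 26.0 at 6 h, and without the filter its log2 change at 6 h was 3.92 ± 0.79 (adjusted p = 0.00318, limma). GH3.1 (5.13 ± 0.39) and WES1 (1.99 ± 0.32) stayed above 0 h, and GH3.3 had a change of 0.34 ± 0.46 (GH3 list adjusted p = 0.0716, camera; 2 of 4 rose by both counts). IAA29 (3.21 ± 0.45) and IAA30 (3.14 ± 0.61) rose (list adjusted p = 0.0617; 2 of 3 by both counts). The GH3 and Aux/IAA lists were called under 4 and 7 of 17 alternatives, and neither with an estimated correlation (adjusted p = 0.267 for each, camera). In the expansin and XTH list EXPA4 (6.22 ± 0.48) and EXPA15 (3.44 ± 0.38) rose and XTH20 (-2.34 ± 0.36) fell, by both counts, and the list was not called (adjusted p = 0.175). WAG2, a kinase gene of auxin transport, rose (1.53 ± 0.49).

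SIM, which encodes an inhibitor of cyclin-dependent kinases, fell by 2.52 ± 0.55. GSO1, a receptor kinase gene that the endodermis needs to seal its Casparian strip, fell by 3.83 ± 0.50 and was the only tested member of the endodermis list. AT1G09750, the tested cortex marker, had a change of -1.41 ± 0.55 (adjusted p = 0.0692, limma). Alone in its list, it passed only at an unadjusted p under 0.05. WRKY53, STZ, AT3G12730 and EXPA18 were not called by either count. Chloroplast-encoded transcripts had a median of 0.02, which was -0.01 under quantile normalization, and 0 of 69 called by either count (limma; 2 higher at an unadjusted p under 0.05; list adjusted p = 0.411, camera).

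By the same rule the largest rises at 6 h were AT3G28420 (7.11 ± 0.48), AT4G15830 (6.47 ± 0.38), PUCHI and AT1G03820 (6.34 ± 0.38), followed by EXPA4, AT1G05577 (6.14 ± 0.94), TBL36 (5.6 ± 0.34), AT3G15550, AT3G01490 and AT2G23530. The change and rank of AT3G28420, which started from a signal of 3.8 ± 0.99, depend on the pseudocount. The changes and ranks of AT1G05577, AT3G15550, AT3G01490 and AT2G23530 depend on it too, with mean signals of 8.65, 8.75, 8.9 and 8.2 at 0 h. After AT4G30450 the largest falls were AT3G62040 (-8.23 ± 0.41), MSRB5, a methionine sulfoxide reductase gene (-7.45 ± 0.51), ATSBT5.2 (-7.20 ± 0.40) and AT3G53980 (-6.74 ± 0.80). The peroxidase gene AT5G66390 fell by 6.47 ± 1.19, with changes of -9.42 in the brighter and -3.52 in the dimmer arrays. AT1G48750, AT5G10580, AT2G21560 and AT4G30170 had changes of -6.41 to -5.99. Mean signals at 6 h were 10.65 for AT3G62040, 10.75 for ATSBT5.2, 1.35 for AT2G21560 and 4.3 for AT4G30170. The sizes and ranks of these falls therefore depend on the pseudocount. ICU2 was not called without the filter (adjusted p = 0.0966, limma) and WAG2 not with the hybridisation controls as a block (0.0552), and without replicate 2 at 0 h or replicate 1 at 6 h neither was called (0.142 and 0.166 for ICU2, 0.178 and 0.200 for WAG2), nor HTB1 (0.0771 and 0.172). Without replicate 2 at 0 h or replicate 1 at 6 h neither the DNA replication list nor the polymerase list was called (adjusted p = 0.0632 and 0.0785 for both lists, camera).

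**Figure D3:**
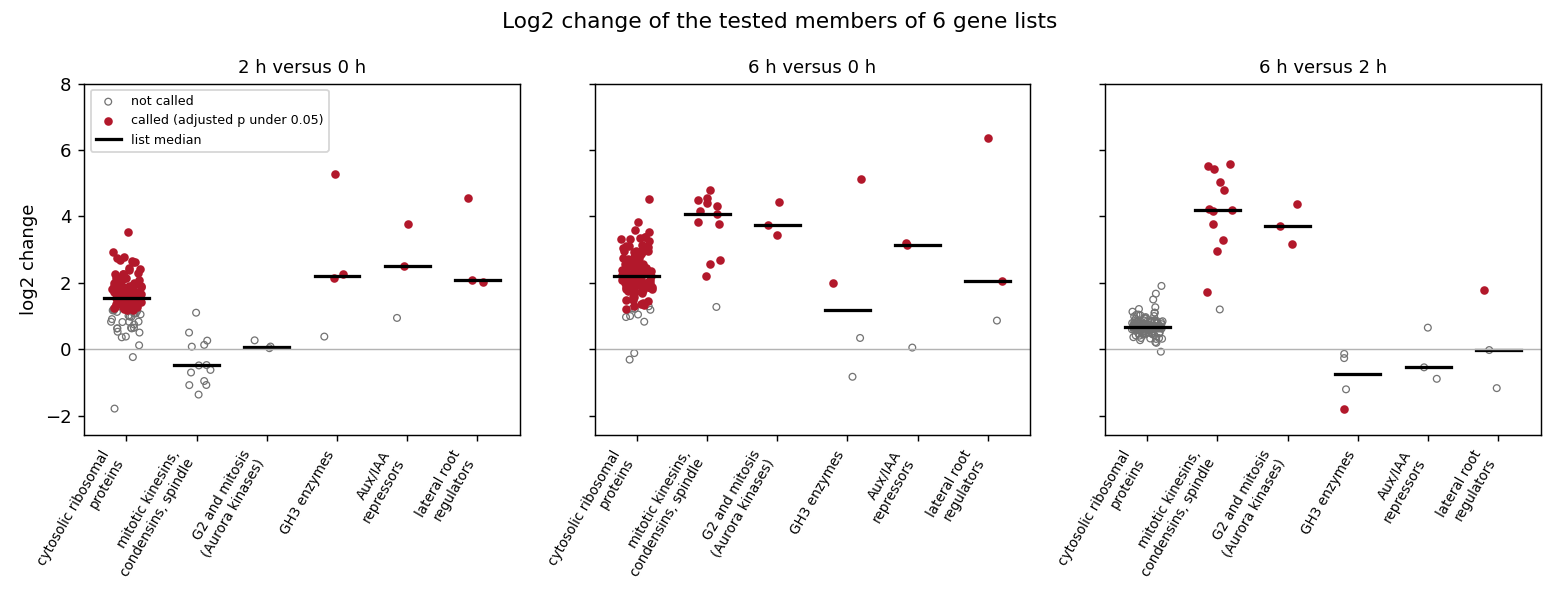
Log2 change of each tested member of 6 gene lists in the 3 comparisons; filled points are called at an adjusted p under 0.05, open points are not, and black bars are list medians. The kinesin and condensin list has medians of -0.49, 4.06 and 4.20 from left to right, and the ribosomal protein list medians of 1.54, 2.22 and 0.67.

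Calls at 2 h and 6 h overlapped. Of the probe sets higher at 2 h 899 (90.7%) were also higher at 6 h, and of those lower at 2 h 483 (85.9%) were also lower. These overlaps were 426 and 177 without replicate 1 at 2 h and 340 and 107 without replicate 2 at 2 h, and the shared falls were 217 after centring on the median and 274 without the intensity trend. Both comparisons use the same 0 h arrays. In 100 simulations of unchanged groups the overlap averaged 0.01 higher and 0.02 lower and reached 1 at most. With no change simulated few calls could arise, so these overlaps cannot show how much the shared arrays add where many probe sets are called. Independent lists would share 167 and 95.3. Log2 changes correlated at 0.741 across probe sets, which are not independent replicates (simulated 0.50), with a covariance of 1.04 against a simulated 0.109, a difference of 0.932. With 1 of the 0 h arrays in each comparison, a split chosen after seeing the data, the correlation was 0.480 or 0.602 and the covariance 0.803 or 0.919, depending on which array served which comparison. Then 764 or 776 probe sets were higher in both comparisons, against 175 or 154 for independent lists, and 306 or 286 lower, against 79.3 or 58.6 (limma). The lone 0 h array was assumed to vary like the other groups. Both fits took the spread of each probe set from the same arrays at 2 h and 6 h. Probe sets with a small spread are called more easily in both, so independent lists are not a full baseline for these overlaps.

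Between 2 h and 6 h all 3 Aurora genes and 12 of 13 mitotic kinesin, condensin and spindle genes rose, while the auxin-conjugating gene GH3.3 fell back. With an estimated correlation neither list was called (adjusted p = 0.118 and 0.0880). AUR1 rose by 4.36 ± 0.36, 3xHMG-box2 by 5.42 ± 0.38 and PRL by 1.87 ± 0.30. GH3.3 and WRKY53 fell, with changes of -1.81 ± 0.46 and -2.17 ± 0.41. The Casparian strip gene GSO1 fell by 4.04 ± 0.50, and 2 peroxidase genes, AT5G66390 and AT1G44970, had changes of -6.40 ± 1.19 and -5.53 ± 1.01. On replicates 1 and 2 at 6 h, AT5G66390 had signals of 327.6 and 2.6 and AT1G44970 of 203.1 and 5. From 2 h to 6 h 427 probe sets were higher and 763 lower (8.72% of those tested, limma), of which 214 and 348 had 1 named locus. The actin 3' to 5' ratio was higher on both arrays at 6 h (4.48 and 3.84) than at 2 h (2.98 and 1.37), and that of GAPDH was not (4.37 and 3.42 against 4.73 and 3.93).

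Of the 13 kinesin, condensin and spindle genes 12 rose (13 adjusted over the list alone), with a median of 4.20, and of 4.03 and 4.15 in the brighter and dimmer arrays (adjusted p = 2.88e-16, camera; adjusted p = 0.0880 with an estimated correlation). AT5G60930 (5.58 ± 0.71), AT3G44050 (5.53 ± 0.68) and KINESIN-12B (5.04 ± 0.80), all kinesin genes, were among them. The Aurora genes AUR1, AUR2 (3.70 ± 0.55) and AUR3 (9.02-fold) all rose, by both counts (adjusted p = 1.30e-05, camera; adjusted p = 0.118 with an estimated correlation), with medians of 3.59 and 3.81. Ribosomal protein genes had a median of 0.67, or 0.57 relative to all tested probe sets. The list was called (adjusted p = 8.43e-12, camera; adjusted p = 0.376 with an estimated correlation), with 117 of 118 changes above 0, medians of 0.55 and 0.79, and 0 members called by either count (limma; 27 higher and 0 lower at an unadjusted p under 0.05).

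Chloroplast-encoded transcripts were called higher as a list, with a median of 0.41, or 0.32 relative to all tested probe sets, and 0 of 69 members called by either count (limma; 1 higher at an unadjusted p under 0.05). The list's adjusted p was 0.0240 by camera (adjusted p = 0.720 with an estimated correlation). The change was 0.86 in the brighter and -0.15 in the dimmer arrays, and the median was 0.20 without replicate 2 at 2 h (adjusted p = 0.222) and 0.03 without replicate 2 at 6 h (adjusted p = 0.773). PRL was the 1 called of 4 DNA replication genes by either count (list adjusted p = 0.0700, camera). AT3G42660 (1.34 ± 0.38) was the 1 called of 3 genes of the polymerase list with RFC and RPA by either count (0.0823). Other lists were not called, though that of nucleolar genes was under 4 of 17 alternatives, both blocks among them (adjusted p = 0.376 with an estimated correlation, camera). They were nucleolar genes (adjusted p = 0.0573, camera), GH3 (0.0853, 1 lower by both counts), histones (0.462), expansins and XTHs (0.536, EXPA15 higher at 1.70 ± 0.38 and XTH20 lower at -2.11 ± 0.36, by both counts), Aux/IAA (0.536) and lateral root regulators (0.965). In the last, the median was -0.03 while the test pointed to a rise: PUCHI rose by 1.79 ± 0.43, LBD29 had a change of -0.03 ± 0.41 and LBD16 one of -1.17 ± 0.33 (adjusted p = 0.0501, limma), and adjusted over the list alone 1 rose and 1 fell. LBD16 was called under 7 of 17 alternatives. SIM fell by 2.65 ± 0.55. WAG2, alone in its list, passed only at an unadjusted p under 0.05, and STZ, which was lower, only when adjusted over its list alone. AT3G12730, AT1G09750 and EXPA18 were not called by either count.

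By the same rule the largest rises from 2 h were AT4G15830 (6.77 ± 0.38), AT5G48310 (6.02 ± 0.54), AT5G48460 (5.92 ± 0.89) and AT3G51720 (5.91 ± 0.70), with AT5G17160, AT3G27330 and AT1G05577 at 5.26 to 5.71. The largest falls were the peroxidase AT5G66390, AT4G30450 (-6.24 ± 0.39), the dirigent gene AT4G13580 (-5.82 ± 0.68) and AT3G62040 (-5.63 ± 0.41). MSRB5, AT3G53980, AT1G44970, the dirigent gene AT2G39430 (-5.31 ± 0.83), AT3G16330 and AT4G17215 had changes of -5.55 to -4.85. Mean signals at 6 h were 7.5 for AT4G30450 and 10.65 for AT3G62040, so the sizes of their falls depend on the pseudocount. So do the rises of AT5G48460 and AT3G27330, with mean signals of 12.55 and 11.05 at 2 h. With the hybridisation controls as a block 904 probe sets were called, PUCHI (adjusted p = 0.0582, limma) and AT3G42660 (0.0859) not among them, and 526 and 563 were called without replicate 1 or 2 at 2 h and 604 and 521 without replicate 1 or 2 at 6 h. Single arrays ended several calls, at an adjusted p of 0.155 for EXPA15, 0.101 for SIM and 0.0518 for XTH20 without replicate 1 at 2 h, 0.0779 for WRKY53 and 0.0503 for AT1G44970 without replicate 2 at 2 h, 0.204 for PUCHI and 0.253 for AT3G42660 without replicate 1 at 6 h, and 0.252 for GH3.3 without replicate 2 at 6 h (limma).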

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

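The block for the hybridisation controls was chosen after the arrays' control signals were seen, and the genes named here by their pattern were chosen after their values were seen.

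Some probe sets moved in opposite directions at 2 h and 6 h, both versus 0 h. There were 6 that were higher at 2 h and lower at 6 h, and their difference from 2 h to 6 h had adjusted p-values of 0.000322 to 0.00160 (limma). The 4 named ones were AT2G32020, the UDP-glycosyltransferase genes UGT87A2 and UGT73B4, and SUFE2. UGT87A2 had a mean signal of 703 at 0 h, 2143 at 2 h and 283 at 6 h. The opposite course was seen for 2 probe sets, those of AT3G16060 and AT3G17680, whose changes from 2 h to 6 h were 2.99 ± 0.36 and 4.62 ± 0.66 on the log2 scale (adjusted p = 0.000498 and 0.00138). In both classes the change from 2 h to 6 h is the difference of the 2 changes used for the choice. Low p-values for it follow from that choice and are not separate evidence.

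Control signals outside the tested probe sets differed between replicates. The hybridisation controls were 5.32 times as bright on 1 array as on the other at 0 h, 3.26 times at 2 h and 3.41 times at 6 h. The 25S rRNA control differed 1.10-fold, 2.83-fold and 2.23-fold in the same order. Each side of the split by hybridisation controls holds 1 array of each time point, so a block for it leaves every change as it was and alters only the spread. With the block 78.6% of the calls at 2 h versus 0 h, 91.8% at 6 h versus 0 h and 74.7% at 6 h versus 2 h were still made. Changes in the brighter and the dimmer arrays correlated across probe sets, which are not independent replicates, at 0.527, 0.734 and 0.692 in the same order.

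On the array of replicate 1 at 2 h, 660 of the 9099 probe sets below the filter (7.25%) were called present by the authors' detection calls, against 86.5% of those tested.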

How the results depend on the processing

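The block for the hybridisation controls and the split of the 0 h arrays were chosen after seeing the data, and the other alternatives before. Over the genes named, 1930 of 2010 comparisons with an alternative kept the side of the threshold, 72 lost the call, 8 gained it and 0 reversed. For genes and lists, a turn in direction counted as reversed only where the main or the alternative result was called. Of 603 for lists, in which the estimated correlation was not counted, 567 stayed, 29 gained a call, 6 lost it and 1 reversed. With the estimated correlation every list call was lost. Counts of calls stayed within 1.5 times in 224 of 264, the split of the 0 h arrays aside, which left 306 or 286 shared falls (483 before). The cause of the shifts below was not tested unless stated.

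Centring on the median left 240 probe sets lower at 2 h (562 before) and 217 shared falls (483). Without the intensity trend there were 976 calls at 2 h versus 0 h, 653 higher and 323 lower, 486 lower at 6 h versus 2 h, and 274 shared falls. With only the 4 arrays compared, 753 were higher at 6 h versus 2 h. Without the filter 8 lists were called at 6 h versus 2 h (4 before). With an estimated correlation 0 lists were called at 2 h versus 0 h, 0 at 6 h versus 0 h and 0 at 6 h versus 2 h, where the preset gave 5, 7 and 4. That test has 3 degrees of freedom. For GH3 at 2 h the estimated correlation was -0.00060, below the preset 0.01, and its p still went from 4.38e-05 to 0.0254, so correlation within that list was not the cause; for other lists both effects were not separated.

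Leaving out each array in turn leaves 1 group with a lone array, assumed to vary like the other groups. Counts of calls fell without some arrays and rose without others. Calls ranged from 473 to 1595 at 2 h versus 0 h (357 to 1071 higher, 116 to 524 lower), from 3026 to 4489 at 6 h versus 0 h (1443 to 2343 higher, 1569 to 2146 lower), from 521 to 1734 at 6 h versus 2 h (148 to 720 higher, 306 to 1014 lower) and from 2616 to 4072 over time. Shared rises ranged from 340 to 969 and shared falls from 107 to 413. Lists called ranged from 5 to 7, 7 to 9 and 4 to 5. The test of chloroplast-encoded transcripts at 6 h versus 2 h turned direction without replicate 2 at 6 h (median 0.0256, and 0.750 without replicate 1). Over their alternatives, the adjusted p-values (limma) at 2 h versus 0 h ranged from 0.00272 to 0.0953 for GH3.3, 0.00251 to 0.0683 for LBD29, 0.000716 to 0.157 for IAA30 and 0.0188 to 0.276 for PGY1. At 6 h versus 0 h they ranged from 0.0224 to 0.166 for ICU2 and 0.00629 to 0.200 for WAG2, and at 6 h versus 2 h from 0.00328 to 0.204 for PUCHI, 0.00562 to 0.252 for GH3.3 and 0.0130 to 0.253 for AT3G42660.

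Samples of different time points share replicate numbers. Deviations from the group means correlated across probe sets at 0.0565, 0.105 and 0.153 between same-numbered arrays, all positive. The main fit used no block, as fixed before the data were examined. Whether same-numbered arrays share more than the number was not settled. With the number as a block more probe sets were called: 2038, 5106 and 1662, against 1553, 4612 and 1190 without it. The larger sets included 99.8%, 99.6% and 99.8% of those called without the block. With the hybridisation controls as a block the counts were 1242, 4296 and 904, including 78.6%, 91.8% and 74.7%. Folds of probe sets near a signal of 5 are understated by the pseudocount.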

Other observations

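The tests of gene families, of the peroxidase, dirigent and endodermal barrier lists, of short genes, of the scaling and of endodermal cells were chosen after results were seen, as were the genes named here.

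Among 29 families formed from shared gene symbols with at least 5 tested members, 3 were called (UGT, GSTU and NRPB). Of 20 UGT genes, which encode UDP-glycosyltransferases, 10 fell and 0 rose at 6 h versus 0 h (median -1.15, adjusted p = 0.00847, camera; adjusted p = 0.543 with an estimated correlation). UGT76B1 had a change of -3.26 ± 0.56 and UGT74B1 one of -2.84 ± 0.43. Of 7 GSTU genes, which encode glutathione transferases, 5 fell (median -1.73, adjusted p = 0.00847; adjusted p = 0.543 with an estimated correlation), with changes of -3.57 ± 0.38 for GSTU20 and -3.53 ± 0.43 for GSTU27. Both families were also called at 6 h versus 2 h (adjusted p = 0.0135 and 0.00446, camera, and 0.797 for both with an estimated correlation). That comparison uses the same arrays at 6 h, so it is not a separate repeat. Of 6 genes for subunits of RNA polymerase II, 3 rose at 2 h (median 1.3, adjusted p = 0.0206; adjusted p = 0.636 with an estimated correlation) and 5 at 6 h versus 0 h (median 1.78, adjusted p = 0.00847; adjusted p = 0.543 with an estimated correlation). NRPB12 rose by 1.5 ± 0.33 at 2 h and 2.14 ± 0.33 at 6 h versus 0 h. These medians kept their sign under quantile normalization and under centring on the median.

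Among 23 class III peroxidase genes, 13 fell and 1 rose at 6 h versus 0 h (median -1.43, adjusted p = 3.97e-05, camera; adjusted p = 0.0565 with an estimated correlation), and 8 fell and 0 rose from 2 h to 6 h (adjusted p = 3.97e-06; adjusted p = 0.0341 with an estimated correlation). AT3G21770 fell by 4.10 ± 0.35 at 6 h versus 0 h, and AT5G40150 rose by 1.99 ± 0.53. The peroxidase genes AT5G66390 and AT1G44970, whose replicates at 6 h differed as given above, are also in the endodermal barrier list below. Of 8 dirigent genes 6 fell and 1, AT1G58170, rose (median -2.57, adjusted p = 0.00351; adjusted p = 0.107 with an estimated correlation). From 2 h to 6 h 4 of them fell (adjusted p = 4.01e-06; adjusted p = 0.0341 with an estimated correlation). The peroxidase and dirigent lists hold genes already named above for their large falls, such as AT5G66390 and AT4G13580. The adjustment covered only these and the endodermal barrier list. Their p-values are thus not support from separate data. At 2 h versus 0 h neither list was called (adjusted p = 0.166 and 0.845), but 6 of the 23 peroxidase genes had already fallen and 0 had risen, among them AT1G49570 (-3.43 ± 0.56) and AT3G21770 (-2.22 ± 0.35), and 1 dirigent gene, AT1G58170, had risen (1.57 ± 0.38). The peroxidase median at 2 h was -0.27, and 0.0032 after centring on the median. Several probe sets peaked at 2 h: 48 were higher at 2 h than at 0 h and then fell, among them GH3.3, WRKY53, WRKY6 and AT4G37290, whose mean signal was 44.8, 881 and 126 at 0 h, 2 h and 6 h. Both calls use the same arrays at 2 h, so an error on these arrays would give the same course. GH3.3 and WRKY53 lost calls when an array at 2 h was left out.

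The rise of ribosomal protein transcripts at 6 h may reflect labelling that favours short transcripts, or the authors' scaling. The first as the whole cause is argued against by 49 other genes with a span of at most 800 bases, whose transcripts can be no longer, and a mean signal at or above the 5th percentile of the list: the central 95% of their bootstrapped median log2 change ended at 0.068, against 2.22 for the ribosomal protein list. These genes went both ways, with 12 called higher and 15 lower at 6 h versus 0 h (limma). Transcript lengths themselves were not used here, so a smaller part of transcript length in the rise stays open. The scaling as the whole cause is argued against by a list median of 1.97 under quantile normalization, the lower of 2 other scalings. A response of the cells to time on auxin stays open, as a hypothesis found and tested on the same data. So do a change in the mix of sorted cells, which was not tested for this list, and RNA quality, for which the controls differed. The actin 3' to 5' ratio was 4.48 and 3.84 at 6 h against 2.22 and 1.40 at 0 h. Both ubiquitin ratios at 6 h (8.81 and 10.7) also lay above those at 0 h (8.31 and 5.99). The GAPDH ratios at 6 h (4.37 and 3.42) lay between those at 0 h (5.78 and 2.68).

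A further hypothesis is that endodermal cells were sorted with the pericycle at 0 h and 2 h and may have been fewer at 6 h. Of 42 listed genes of the Casparian strip and suberin 9 were tested (at 6 h versus 2 h, median -4.78, 7 of 9 lower, adjusted p = 9.52e-09, camera; adjusted p = 0.0587 with an estimated correlation; at 6 h versus 0 h adjusted p = 3.97e-05 and 0.118; at 2 h versus 0 h 0.887, with 0 called). All 7 with a mean signal of at least 500 at 2 h were lower at 6 h, with changes of -6.40 to -3.18, so that 0% of them had a change above -1, and the brightest, AT5G66390, had a mean signal of 4503 at 0 h, 4233 at 2 h and 165 at 6 h. All 7 were also higher on replicate 1 than on replicate 2 at 6 h, by 0.02 to 5.45 on the log2 scale. Fewer endodermal cells and lower expression in the sorted cells cannot be told apart: 7 genes are few, 5 of them were already among the named falls when the list was made, 4 are also in the peroxidase or dirigent lists, how many of them pericycle cells also express was not tested, the actin 3' to 5' ratio was higher on both arrays at 6 h than at 2 h while that of GAPDH was not (4.37 and 3.42 against 4.73 and 3.93), and the sort on green fluorescent protein should remove endodermal cells.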
